A study of Mus musculus with 2 samples.

How the data were processed

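Heart tissue of B6CASTF1/J male mice aged 14 days was profiled by DNase-seq in 1 group with 2 biological replicates, and no contrast is given by the labels. Each replicate had 2 peak sets, a list of bases with low false discovery rates and a list of footprints, all on mm10. Per the submitters' processing notes, each set was made per replicate from that replicate's filtered alignment, with no pooling. The callers, their versions and the read totals are not given in the sources used here, nor is how reads of the CAST parent were treated on this reference genome, which is that of C57BL/6J. The peak signal was scaled by read depth by the authors, per the submitters' processing notes, which name a read-depth normalized track made from the same alignment, and the exact scaling is not stated. The deposited FDR values give the false discovery rate of DNase cleavage for runs of adjacent bases, and only runs with FDR under 0.05 are listed. Footprints were made by the authors from the alignment and the FDR list, and the other column of the deposited footprint lists holds 0.01 throughout, whose meaning is not stated and which was not used.

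The larger peak set was taken as the main set and the smaller as an alternative. In the smaller set every peak held a base with FDR under 0.001, against 68.1% and 66.8% of the larger set in replicates 1 and 2. That choice was made on seeing the lists and before any overlap was computed. The plan called for wider accessible regions, which were not among the deposited sets, so the bases with FDR under 0.05 took their place. Gene lists, the consensus sequences, the settings and a first set of alternatives were fixed before the data were examined. The percentiles 97.5 and 2.5 and the ratio of 1.5 used for counting lists and motifs were chosen after values were seen.

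Peaks counted as shared where 50% of their length was covered by peaks of the other replicate, and 100 circular shifts along each chromosome gave the background. Merged regions with a peak in each replicate were called shared, and the highest peak in a region gave its value. Promoters were 1 kb either side of any start of a protein-coding gene in GENCODE M21, and a gene's value was the highest peak in its windows. A peak that reached the starts of several genes counted for each. A peak's class was promoter, then exon, intron or intergenic by its middle base. The text names 21 fixed genes, the 3 list members with the highest value and up to 3 with no promoter peak, the 10 strongest shared regions away from promoters, and the 5 highest and 5 lowest motifs. Other names were chosen after their values were seen.

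The 18 gene lists hold 319 entries and 310 different genes, all of which were found. Each list was set beside 10000 random lists of the same size, matched on gene length decile and drawn with replacement from all protein-coding genes, list members included. The percentile is the percentage of random lists below the list, with ties split evenly, and describes these libraries without a p-value. A second matching used the CpG content of 500 bp either side of the 5' end. Shared regions were counted in each gene's body and 10 kb either side. For motifs, the share of footprints with a match to each of 31 consensus sequences on either strand, with 10 bp either side, was divided by the share in windows moved 200 bp either way that touched no footprint. Alternatives used 10 shuffles of each consensus, windows inside peaks, or windows weighted to the GC content of footprints in 20 bins. Windows inside peaks were set against all footprints, including those outside peaks. Intervals are exact 95% intervals from the counts, and a count of 0 is given the limit of 3 counts. For repeated sequence, each 36-base word of a region was looked up on both strands of the reference.

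On simulated data, overlaps were called as made in 100% of 2000 cases, planted motif matches were found in 100% of 12670 cases, and 4% of 200 unselected lists fell outside the central range of random lists. Of 200 simulated lists of 20 genes with 19 open, 100% lay above the high percentile. Means and SDs are over the 2 replicates, and for peak and footprint overlap over the 2 directions of 1 comparison. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used. The reference was GRCm38.p6, the same assembly as mm10. Alternatives covered the overlap required, peak sets, windows, flanks, backgrounds and each replicate alone. Reads, alleles and any comparison between ages, sexes or tissues were not analysed here.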

Results

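DNase-seq, in which the enzyme DNase I cleaves the DNA of nuclei where chromatin is accessible, was done on heart tissue of male mice aged 14 days of strain B6CASTF1/J, a first-generation cross of C57BL/6J and CAST/EiJ mice. There was 1 group with 2 biological replicates. The label of replicate 1 names 3 males, and that of replicate 2 gives no number of animals. Whether hearts were pooled is not stated, so an SD over the 2 replicates may compare a pool with a single heart. The larger deposited peak set held 143122 peaks in replicate 1 and 125118 in replicate 2, which covered 0.974% and 0.889% of the mm10 genome. The peak signal, scaled by read depth by the authors, had a median of 0.780 in replicate 1 and 0.728 in replicate 2. Read totals are not given in the sources used here, so the depth behind each peak is unknown. The lower values, those of 99569 peaks in replicate 1 and 83873 in replicate 2, were tested for a common step. They were whole multiples of 0.00709 in replicate 1 and 0.00597 in replicate 2, within 0.02 of a step. The median peaks thus stood 110 and 122 steps above zero, and stronger peaks were not tested for steps. Footprints, short stretches inside accessible DNA that were protected from cleavage, numbered 350009 and 335568. With a single group and no contrast, the design allowed a comparison of the replicates with each other and of gene lists with random genes, and no test between groups.

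Both libraries shared most of their accessible sites. Of the peaks of replicate 1, 69.9% had at least 50% of their length covered by peaks of replicate 2. Of those of replicate 2, 81.0% were so covered by peaks of replicate 1, with a mean of 75.4% (SD 7.88). These are 2 directions of 1 comparison, so that SD is not a spread between replicates. With the same number of top peaks in both, the shares were 76.7% and 77.9%. Peaks shifted along their chromosomes gave a mean of 0.968% and at most 1.06%. Merging the peaks gave 158036 regions, of which 104208 (65.9%) were accessible in both replicates, 35776 in replicate 1 alone and 18052 in replicate 2 alone. Regions seen in a single replicate were weak, with a median signal of 0.376 for replicate 1 alone and 0.328 for replicate 2 alone, against 1.1 and 0.877 in the shared regions. Across shared regions, which are not independent replicates, Pearson's r of the log2 signal was 0.972. On the authors' scale replicate 1 was higher in 80.8% of them. The median log2 ratio of replicate 1 to replicate 2 was 0.31 (SD 0.35), and 99.3% lay within 2-fold of that median. The bases listed with a false discovery rate under 0.05 covered 1.61% and 1.48% of the genome, and their Jaccard index, the shared bases as a percentage of the bases in either replicate, was 71.1%, against 0.855% after shifts. The shared bases were 79.9% of those of replicate 1 and 86.7% of those of replicate 2.

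**Figure D1:**
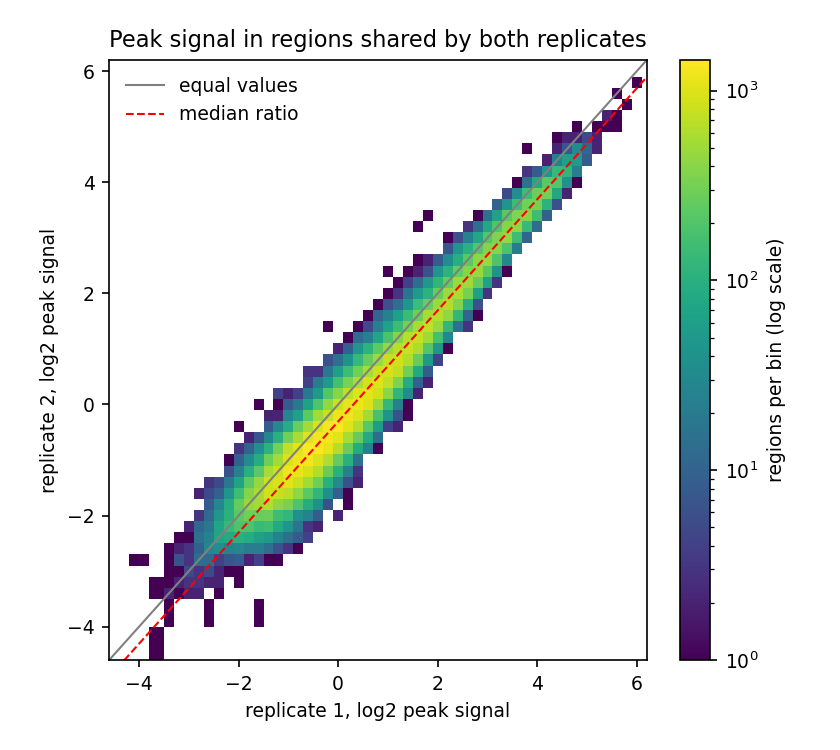
Log2 peak signal of replicate 1 (x axis) and replicate 2 (y axis) in the 104208 regions accessible in both, with colour for the number of regions per bin on a log scale. The dashed line, drawn at the median log2 ratio of 0.31, lies on the replicate 1 side of the line of equal values.

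Accessible sites lay at gene starts far more often than the genome's make-up alone gives. Of all peaks, 25.1% ± 1.6 (SD, n = 2) overlapped the 1 kb either side of a start of a protein-coding gene, windows that covered 3.59% of the genome. Introns held 33.1% ± 1.02 of the peaks, intergenic DNA 37.5% ± 0.80 and exons 4.31% ± 0.27. Promoter peaks were the strongest class, with a median signal of 1.65 ± 0.01 against 0.678 ± 0.06 in exons, 0.673 ± 0.04 in introns and 0.615 ± 0.03 in intergenic DNA. They were also shared more often, since 77.0% of merged regions at promoters were accessible in both replicates and 62.6% of those elsewhere. The X chromosome, of which males carry a single copy, had 21.2 peaks per Mb in replicate 1 and 19.3 in replicate 2, fewer than any autosome, and the lowest autosome was chromosome 3 with 44.0 and 37.6. The median signal on X was 0.454 and 0.424, and the lowest autosomal medians, on chromosome 13, were 0.681 and 0.621. Of 21911 protein-coding genes, 15069 (68.8%) had a promoter peak in both replicates, 28.3% in neither and 2.90% in a single replicate. Genes with a peak in both are called open here.

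Promoters of heart muscle genes were open more often than those of random genes. In the list of cardiomyocyte contraction and calcium handling, 32 of 35 genes were open, above 99.7% of 10000 random lists matched on gene length, which averaged 73.6%. Signal was highest at Tpm1, which encodes a tropomyosin of the thin filament, with 22.2 ± 1.70 (SD, n = 2). Myom1, a protein of the sarcomere's M-band, had 20.9 ± 1.86, and Myl4, the atrial light chain of myosin, had 18.8 ± 1.95. The peaks behind these last values also touched the starts of Myl12a and Myl12b (for Myom1) and of Cdc27 (for Myl4). Counting only peaks at the promoter of 1 gene left Myom1 with 1.03 ± 0.25 and Myl4 with 0.461 ± 0.02, and at the 5' end of the gene alone Tpm1 had 6.05 ± 0.74. The heart troponin genes Tnnt2 and Tnni3 had a low promoter signal among open genes. Tnnt2, cardiac troponin T, had 2.09 ± 0.58, at percentile 46.2 of the 21911 genes, and Tnni3, the adult cardiac troponin I, had 2.08 ± 0.84, at percentile 46.1. Genes without a peak counted as 0 in these percentiles, and 28.3% of genes had none in either replicate. Both genes thus stood below most open genes. Tnni1, the troponin I of the fetal heart, had 1.77 ± 0.39 (5.43 ± 0.09 with windows of 2 kb). The natriuretic peptide genes Nppa and Nppb had 0.390 ± 0.01 and 1.81 ± 0.56, and Nppa had no promoter peak in the smaller peak set. Myl7, the regulatory light chain of the atria, had a promoter peak in replicate 1 alone and Trdn, encoding triadin of the calcium release complex, in replicate 2 alone. The median gene of the list had 6 shared accessible regions in its body and 10 kb either side, above 97.9% of random lists. The smaller peak set ended both calls, with 29 open genes (96.6% of random lists below) and a median of 4 regions (87.5%), and without regions within 1 kb of any start the list lay above 96.4%.

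Of the neighbouring myosin heavy chain genes on chromosome 14, Myh6, the fast form of the adult mouse heart, was open, and Myh7, the slow form of the fetal ventricle, was not. Myh6 (54941921 to 54966927, minus strand) had a promoter signal of 1.5 ± 0.54 (SD, n = 2). Its peak spanned 54966441 to 54966880 in replicate 1 with a signal of 1.88, and 54966661 to 54966720 in replicate 2 with 1.12. Myh7 (54970684 to 54994626, minus strand) had no promoter peak in either replicate. Between the genes, a peak from 54968421 to 54968800 had a signal of 2.43 in replicate 1, and its counterpart in replicate 2 ended at 54968720 with 1.82. Both covered the start of the antisense RNA Mhrt, at 54968678. With windows of 2 kb, which reach that peak, the value of Myh6 was 2.12 ± 0.43. Upstream of Myh7, a peak from 55003901 to 55004240 had a signal of 2.24 in replicate 1 and 1.60 in replicate 2. No other age was in the data, so a change with age was not analysed here.

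**Figure D2:**
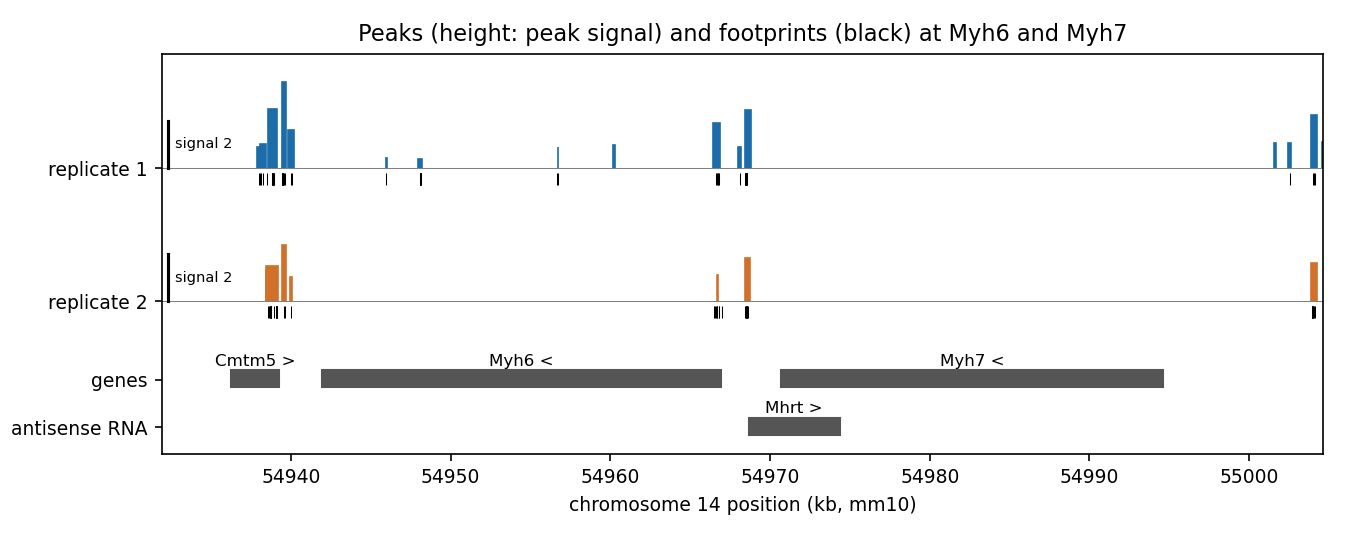
Peaks of each replicate (height to scale with the peak signal, bar of 2 units at the left) and footprints (black) over Myh6 and Myh7 on chromosome 14, in kb of mm10, with genes drawn as grey bars and arrowheads for strand. Both replicates have a peak at the start of Myh6 and none at the start of Myh7.

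Cardiac transcription factor genes stood out by the number of accessible regions around them. The median gene of the list had 11 shared regions in its body and 10 kb either side, above 99.99% of random lists, whose medians averaged 4.61. Gata4, a zinc finger factor of early heart development, had 26 such regions and a promoter signal of 6.97 ± 0.65 (SD, n = 2). Mef2c, a MADS-box factor of muscle, had 16 regions and 5.23 ± 0.35, and Hand2, a basic helix-loop-helix factor of the right ventricle, had 16 and 4.85 ± 0.80. Tbx5, the T-box factor mutated in Holt-Oram syndrome, had 10 regions and 0.907 ± 0.10, and Nkx2-5, a homeobox factor of the cardiac lineage, had 4 and 2.36 ± 0.26. At the 5' end alone Gata4 had 2.27 ± 0.35, Nkx2-5 had 0.731 ± 0.08 and Tbx5 had 0.743 ± 0.17, while Mef2c had no peak in either replicate. With windows of 500 bp Tbx5 had a peak in replicate 1 alone. The strongest promoters of the list were those of Esrra, a regulator of mitochondrial genes, with 23.9 ± 5.72, Hey2, a Notch target of the ventricle, with 17.5 ± 0.44, and Mef2a, the main MEF2 factor of the heart after birth, with 15.1 ± 1.12. Open promoters numbered 21 of 22, above 99.3% of random lists matched on length but 90.2% of those matched on promoter CpG content. Hand1, a factor of the embryonic left ventricle, was the gene without a promoter peak in either replicate.

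Genes of fuel use by the heart were open throughout, and those of the fetal heart mostly so. All 26 genes of fatty acid oxidation and mitochondrial respiration were open, a count that no random list reached. The highest signals were at Cycs, encoding cytochrome c, with 20.7 ± 3.37 (SD, n = 2), Slc25a4, the adenine nucleotide carrier of heart and muscle, with 16.7 ± 2.97, and Acadm, the medium-chain acyl-CoA dehydrogenase, with 16.1 ± 1.99. With peaks that touched the promoter of 1 gene only, 19 of the 26 were open, above 93.2% of random lists, since Hadha and Hadhb share a start region, as do Sdha and Ccdc127. Among genes of the fetal heart that return in disease, 8 of 10 were open, above 92.9% of random lists. Myl4, whose peak also touched the start of Cdc27, had the highest value of this list too. It was followed by the smooth muscle gene Tagln with 2.40 ± 0.52 (1.12 ± 0.10 with windows of 500 bp), Nppb and Tnni1. Replicate 1 alone gave 9 open genes of the 10, above 98.1% of random lists.

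Genes of the heart's other resident cells were open as well. In the endothelial list, 21 of 22 genes were open, above 99.7% of random lists, and the median gene had 9 shared regions around it, above 99.99%. Ets1, a factor of blood vessel growth, had 16.3 ± 2.60 (SD, n = 2; 1.1 ± 0.26 at its 5' end alone), Eng, encoding endoglin, had 5.88 ± 0.58, and Vwf, encoding von Willebrand factor, had 5.41 ± 1.80. Pecam1, a junction protein of endothelium, had 17 regions and a promoter signal of 1.39 ± 0.27, and Kdr, the main receptor for VEGF, had 4.45 ± 0.51. Plvap, a protein of fenestrated vessels, had no promoter peak in either replicate, and at their 5' ends alone neither had Vwf and Pecam1. At 5' ends alone the endothelial count fell to 18, above 92.6% of random lists, and without flanks its median of 3.5 regions lay above 95.8%. All 18 fibroblast genes were open, above 99.8% of random lists, with Fn1 (fibronectin) at 9.98 ± 1.86, Vim (vimentin) at 7.75 ± 0.73 and Col1a1 (a chain of collagen I) at 7.54 ± 1.06. Tcf21, a factor of cardiac fibroblast precursors, had 2.63 ± 0.26. The upper 50% of peaks by signal left 15 fibroblast genes open (90.3% of random lists below), and the smaller peak set 16 (94.8%). The fibroblast median of 5.5 regions around genes lay above 92.1% of random lists, and replicate 1 alone gave 8.5 and 99.1%. All 14 genes of smooth muscle and pericytes were open, above 99.3%, with Smtn (smoothelin) at 8.55 ± 1.70, Myh11 (smooth muscle myosin) at 3.88 ± 0.90 and Kcnj8 (a channel of pericytes) at 3.84 ± 0.60. A stronger peak within 2 kb raised Smtn to 15.6 ± 2.44, and at its 5' end alone Smtn had no peak. Epicardial genes, 7 of 10 open, matched random lists (52.1% of them below), with Tbx18 at 4.36 ± 1.28, Aldh1a2 at 3.85 ± 0.12 and Wt1 at 1.93 ± 0.30, and no peak at Upk3b.

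Blood and fat genes gave a mixed picture. Among leukocyte genes 11 of 18 were open, above 31.9% of random lists. Coro1a, an actin regulator of lymphocytes, had 7.21 ± 1.51 (SD, n = 2), Spi1, the master factor of myeloid cells, had 1.47 ± 0.02 (1.07 ± 0.25 with windows of 500 bp), and Cd68, a macrophage protein, had 1.03 ± 0.23. Coro1a had no peak at its 5' end alone, and Cd68 kept its peak in the smaller set in replicate 1 alone. Ptprc, the pan-leukocyte gene for CD45, had no promoter peak in either replicate, nor had the lymphocyte genes Cd3e and Cd79a. The call for leukocytes turned on the comparison, with 98.5% of CpG-matched random lists below but 0.26% below for the upper 50% of peaks and 0.08% for the smaller peak set, both with 5 open genes. Among erythroid genes 5 of 12 were open, above 13.0%, with Epor (the erythropoietin receptor) at 2.77 ± 0.41 and Tal1 (a factor of blood and endothelium) at 2.66 ± 0.17. Alas2, Gata1 and Hba-a1, the genes of heme synthesis, red cell identity and alpha globin, had no promoter peak. The erythroid list fell to 3 open genes at 5' ends alone (1.84% of random lists below) and in the smaller peak set (2.00%). Among genes of brown and white fat 8 of 12 were open, above 39.9%, led by the lipid droplet genes Plin1 at 3.13 ± 0.42 and Cidea at 2.91 ± 0.13 and by Fabp4 at 2.35 ± 0.03, which capillary endothelium also uses. Adipoq, Cidec and Lep had no promoter peak, and Plin1 had none at its 5' end alone.

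Most listed genes of liver and lung were closed. In the hepatocyte list 2 of 18 genes were open, fewer than in any of the 10000 random lists, namely Afp (fetal albumin) with 2.90 ± 0.32 (SD, n = 2) and Apob (apolipoprotein B) with 1.79 ± 0.27. With windows of 500 bp neither had a peak, and Afp had none at its 5' end alone. Alb, Apoa1 and Cps1, all highly active in liver, had no promoter peak in either replicate, although with windows of 2 kb Apoa1 had 4.56 ± 0.10. In the list of lung epithelium 3 of 12 were open, above 0.65% of random lists and 2.62% of CpG-matched ones. Those were Foxj1, a factor of motile cilia, with 11.1 ± 1.93, Epcam, an epithelial adhesion protein, with 0.696 ± 0.18, and Ager, a gene of alveolar type I cells, with 0.632 ± 0.10. Ager had no peak in the smaller set, and with windows of 500 bp it had a peak in replicate 1 alone. Cldn18, Krt5 and Lamp3 had no promoter peak. With peaks at the promoter of 1 gene only, the lung list lay above 4.47% of random lists.

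Lists of skeletal muscle, neurons and germ cells were less clearly apart. Among skeletal muscle genes 9 of 18 were open, above 6.6% of random lists. Mylpf, a fast myosin light chain, had 14.1 ± 0.34 (SD, n = 2) and Actn3, the fast-fibre actinin, had 12.1 ± 2.0, but both peaks reached starts of neighbours. Without such peaks Mylpf had 0.833 ± 0.38 and Actn3 had none in either replicate, and with windows of 500 bp Actn3 had 0.932 ± 0.12. Casq1, the calsequestrin of skeletal muscle, had 3.11 ± 0.87, Myod1, the skeletal muscle determination factor, had 0.514 ± 0.03, and Atp2a1, Myh1 and Myh2 had no promoter peak. Windows of 500 bp left 4 skeletal muscle genes open, above 0.005% of random lists, with no peak at Casq1 or Myod1. In the smaller peak set Myod1 had a peak in replicate 1 alone, and with windows of 2 kb Atp2a1 had 1.08 ± 0.13. Among neuronal and glial genes 13 of 20 were open, above 12.6%, with the synaptic gene Snap25 at 6.18 ± 0.50, Rbfox3 (the antigen NeuN) at 3.16 ± 0.71 and Syn1 (synapsin) at 2.94 ± 0.58. With windows of 500 bp Snap25 had a peak of 0.234 in replicate 1 and none in replicate 2, and Rbfox3 dropped to 0.459 ± 0.03, as it did at its 5' end alone. Dbh, Elavl3 and Neurod1 had no promoter peak, although windows of 2 kb gave Dbh 1.01 ± 0.16 and Elavl3 1.00 ± 0.05, and 9 open genes in the smaller peak set put the neuronal list above 0.40% of random lists. Among pluripotency and germ line genes 6 of 14 were open, above 4.76% of length-matched and 0.05% of CpG-matched random lists. Tex14, a gene of germ cell bridges, had 14.0 ± 2.15 from a peak that Rad51c shares, and 2.33 ± 0.82 without it. Dazl, a germ cell RNA-binding protein, had 8.52 ± 1.47, Esrrb, a factor of stem cells, had 1.86 ± 0.06, and Pou5f1, the gene of OCT4, had 0.973 ± 0.17, with no peak in windows of 500 bp or at its 5' end alone. Ddx4, Dppa3 and Dppa5a had no promoter peak.

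Every gene of the cell division and housekeeping lists was open. All 18 cell division genes were open, above 99.95% of length-matched random lists but 80.1% of CpG-matched ones, with Ccna2 (cyclin A2) at 16.5 ± 2.30 (SD, n = 2), Mcm5 (a replication helicase subunit) at 16.4 ± 4.90 and Birc5 (survivin) at 14.1 ± 1.65. All 20 housekeeping genes were open, above all length-matched lists and 98.1% of CpG-matched ones. Rplp0, a ribosomal protein, had 22.9 ± 5.35, Actb, cytoplasmic actin, had 20.1 ± 3.02, and Ppia, cyclophilin A, had 18.5 ± 2.09. The median housekeeping gene had 5 regions around it, above 99.4% of random lists, but leaving out regions within 1 kb of any start gave 1, above 68.5%. Transcription was not analysed here.

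**Figure D3:**
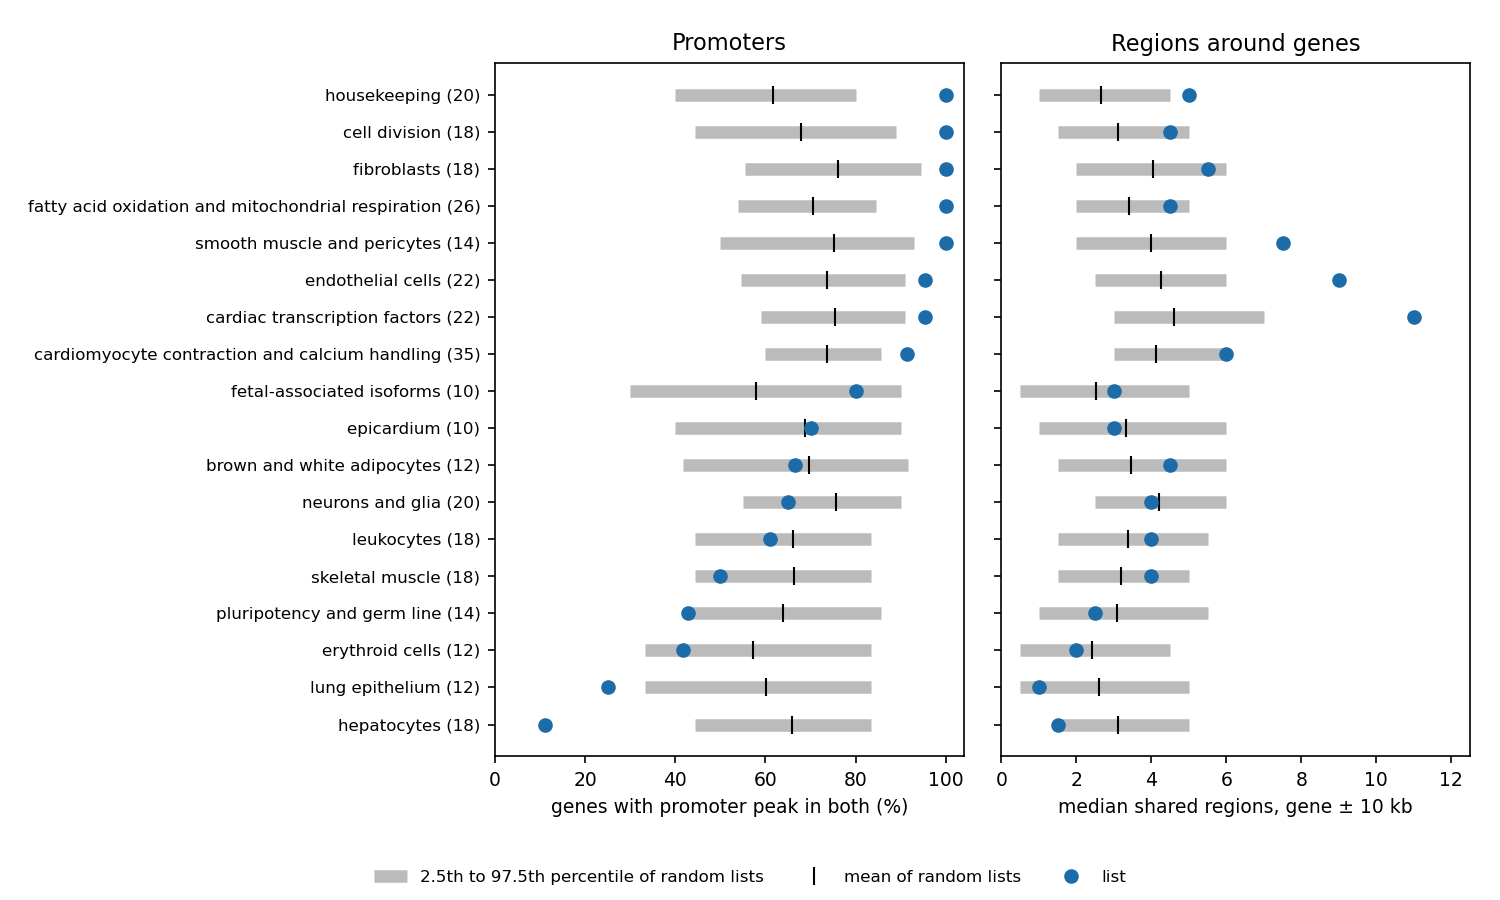
Percentage of each list's genes (number in brackets) with a promoter peak in both replicates (left) and the median number of shared regions in the gene body and 10 kb either side (right), as blue points, beside the central 95% (grey bars) and mean (black ticks) of 10000 random lists matched on gene length. In the left panel 8 lists lie right of the grey bars. These are heart muscle, cardiac transcription factors, fatty acid oxidation, endothelial cells, fibroblasts, smooth muscle, cell division and housekeeping. Hepatocytes and lung epithelium lie left of the bars.

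The strongest sites away from promoters often lay in repeated sequence. The region with the highest signal, 103.7 kb from Esp38 on chromosome 17 (39846781 to 39846900), reached 60.0 ± 0.65 (SD, n = 2), and an exon of Lars2 on chromosome 9 (123461901 to 123462080) reached 51.0 ± 1.00. Next came regions near Gm15319 on chromosome 8 with 40.6 ± 6.54, in an intron of Kpna1 with 40 ± 6.21, near Igf2bp3 with 37.5 ± 4.90 and in introns of Il31ra with 30.9 ± 2.83 and Zc3h7a with 29.4 ± 0.78. The last of the 10 were near Gm31371 with 27.2 ± 6.39, near Gm42791 with 27.2 ± 5.95 and in an exon of Cers5, nearest to the start of Cox14, with 26.8 ± 2.31. In 8 of the 10, all but those near Gm42791 and Cox14, over 50% of the 36-base words occur elsewhere in the reference too, so reads there could belong to more than a single place. After these 10, the strongest region without such copies, picked after the values were seen, lay 17.3 kb from Nacc2 on chromosome 2 (26140361 to 26140700) with 25.9 ± 3.26. Others were 72.7 kb from Irf2bp2 on chromosome 8 (126666561 to 126666760) with 25.5 ± 2.5 and in an intron of Per1, a clock gene, on chromosome 11 (69097001 to 69097240) with 23.8 ± 5.63.

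Relative to windows nearby, the sites of CTCF and REST were the most frequent in footprints. CTCF, the insulator protein, had its consensus in 6086 footprints of replicate 1 and 5663 of replicate 2, against 48 and 43 of the windows 200 bp away, a ratio of shares of 226 ± 1.24 (SD, n = 2), with exact 95% intervals from counting of 169 to 305 and 168 to 313. REST, the repressor of neuronal genes outside the nervous system, had 247 and 234 footprints against 3 and 2 windows, a ratio of 174 ± 39.1, with counting intervals of 49.4 to 713 and 55.1 to 1672. NRF1, a factor of mitochondrial gene promoters, had 34.4 ± 2.96 and NFI, a family of dimeric factors, 32.0 ± 5.23. RFX, a factor of cilium genes, was found in 37 and 31 footprints against 2 and 6 windows, a ratio of 32.8 in replicate 1 (8.46 to 281) and 8.89 in replicate 2 (3.65 to 26.1). Below these came CREB with 13.7 ± 0.26, SP/KLF with 8.15 ± 0.17, ETS with 3.62 ± 0.26, AP-1 with 1.72 ± 0.11 and TEAD with 1.19 ± 0.07, a group named after the values were seen. The size of these ratios turned on the setting. Footprints searched without flanks gave CTCF 730 ± 94.4, NRF1 461 ± 16.0, REST 270 ± 112, CREB 27.7 ± 4.15, SP/KLF 22.5 ± 0.59 and AP-1 1.13 ± 0.09, and TEAD fell to 0.737 ± 0.12. Windows with a match there numbered 12 and 13 for CTCF, 2 and 2 for NRF1 and 2 and 1 for REST. The SDs do not cover the counting error of such small numbers. With windows weighted to the GC content of footprints NRF1 had 16.4 ± 0.64, SP/KLF 3.70 ± 0.17 and RFX 34.8 ± 38.0. Against windows inside peaks NRF1 had 13.1 ± 2.91 (6 windows with a match in each replicate), SP/KLF 4.90 ± 0.06 and ETS 1.52 ± 0.05. Against shuffled sites NFI had 12.3 ± 0.04, CREB 6.55 ± 0.06, SP/KLF 5.39 ± 0.12, ETS 1.82 ± 0.04 and TEAD 2.31 ± 0.08. Footprints away from promoters gave RFX 12.4 ± 9.50, NRF1 10.4 ± 2.98, CREB 8.26 ± 0.52 and SP/KLF 4.13 ± 0.03. Those at promoters, looked at after the values were seen, gave NRF1 58.6 ± 9.85, CTCF 52.3 ± 3.99, CREB 21.3 ± 2.36, AP-1 0.993 ± 0.01 and TEAD 0.862 ± 0.01. Those in shared peaks gave REST 275 ± 190, with a match in 3 and 1 windows.

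Sites of GATA, NKX2-5, MEF2, TBX5 and ERR, all bound by factors of the heart, were less frequent in footprints than in windows nearby, under the settings fixed beforehand. GATA had a ratio of 0.596 ± 0.01 (SD, n = 2), NKX2-5 0.653 ± 0.05, MEF2 0.653 ± 0.04, TBX5 0.706 ± 0.00027 and ERR, the site of Esrra and its relatives, 0.631 ± 0.05. FOX, the site of forkhead factors, had 0.576 ± 0.00061. The POU octamer had 0.726 in replicate 1 and 0.665 in replicate 2, so depletion was not limited to sites picked for the heart. Other sites bound by heart factors were not depleted, with 1.24 ± 0.05 for the HAND/TAL E-box, 1.19 ± 0.07 for TEAD, 1.11 ± 0.08 for MEIS and 1.05 ± 0.01 for SRF. NKX2-5, MEF2, TBX5, the POU octamer, the HAND/TAL E-box, MEIS and SRF were named after their values were seen. These directions turned on the background. Windows inside peaks were 37434 of the 620629 windows in replicate 1 and 47943 of the 577338 in replicate 2. They were set against all footprints, inside peaks or not. The footprint counts thus stayed the same, and ratios above 1 there come from a different and much smaller set of windows. MEF2 had 2.05 ± 0.04 against windows weighted to the GC content of footprints, 1.29 ± 0.03 against windows inside peaks and 1.45 ± 0.0040 against shuffled sites. NKX2-5 had 1.09 ± 0.05 against windows inside peaks and 1.49 ± 0.05 against shuffles. TBX5 had 1.13 ± 0.12 inside peaks, ERR 2.39 ± 0.21 and FOX 1.24 ± 0.03 against shuffles, while inside peaks ERR had 1.1 ± 0.28 and GATA 0.972 ± 0.06. GATA had 0.92 ± 0.02 against shuffles, and with GC-weighted windows GATA had 1.00 ± 0.02 and FOX 0.994 ± 0.0064, but SRF 1.62 ± 0.06. SRF fell to 0.798 ± 0.02 against shuffles and 0.802 ± 0.06 without flanks, and MEIS to 0.889 ± 0.07 without flanks. At promoters MEIS had 0.824 ± 0.06, the HAND/TAL E-box 0.811 ± 0.07 and ERR 0.253 ± 0.05, but against shuffles the HAND/TAL E-box had 3.70 ± 0.10 and MEIS 1.68 ± 0.03. Without flanks GATA, MEF2, ERR and FOX fell further, to 0.317 ± 0.02, 0.268 ± 0.04, 0.416 ± 0.15 and 0.197 ± 0.02. The lowest of the 31 consensus sequences were HNF1 of liver and SOX-OCT of stem cells, with 0 footprints in either replicate and 1 window each. A count of 0 allows shares of up to 0.000857% in replicate 1 and 0.000894% in replicate 2, so no depletion of HNF1 or SOX-OCT was detectable at this depth. Intervals and limits cover counting error only.

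**Figure D4:**
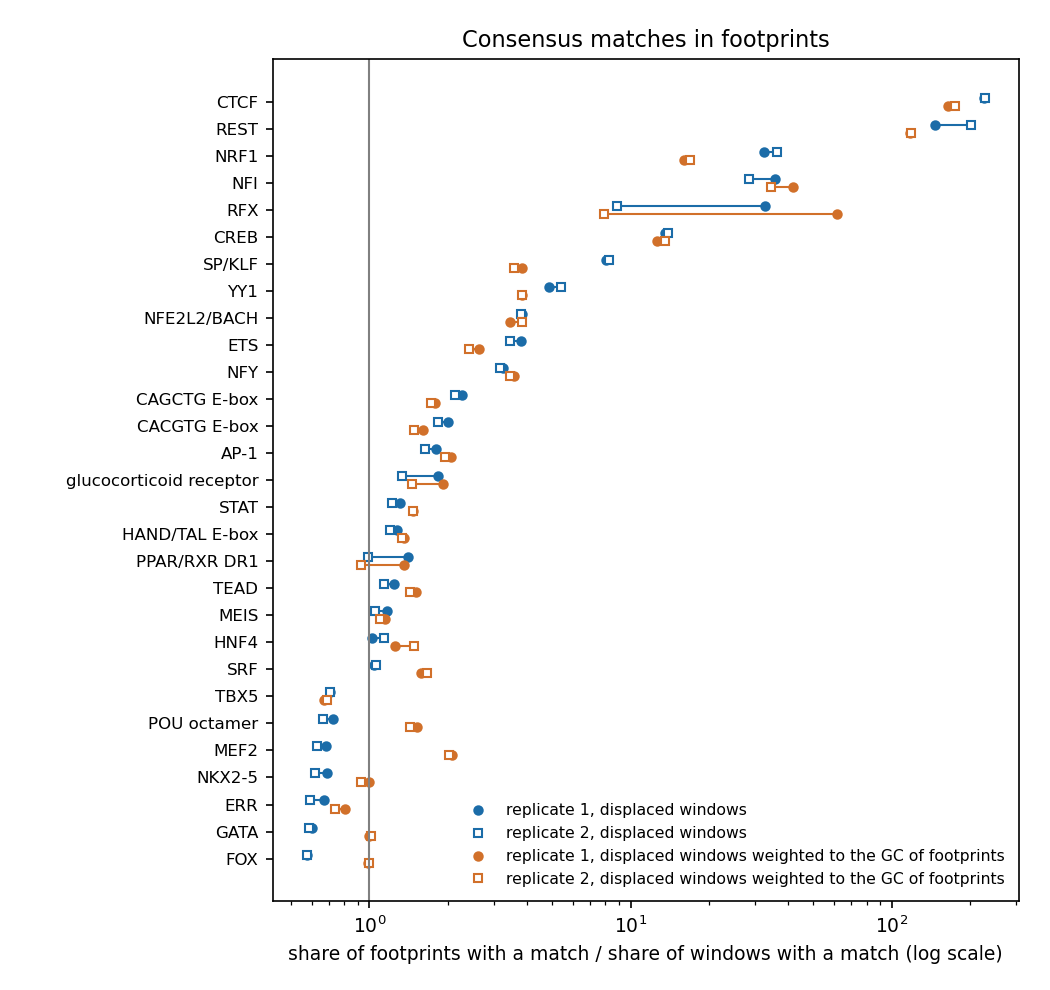
Share of footprints with a match to each consensus divided by the share of windows 200 bp away (log axis), for replicate 1 (circles) and replicate 2 (squares), with all windows (blue) or windows weighted to the GC content of footprints (orange), and lines joining the replicates. HNF1 and SOX-OCT, with 0 footprints, are left out, and MEF2 moves from 0.653 to 2.05.

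In the 76151 shared regions away from promoters, taken whole, a comparison chosen after the footprint values were seen, CTCF sites were 100 times as dense per Mb as in flanks 1 kb away and REST sites 82.7 times (185 sites against 4). NFI sites were 13.4 times as dense, RFX sites 5.07 times (17 against 6), sites of the glucocorticoid receptor, a hormone-activated factor, 4.24 times, ETS sites 3.54 times, AP-1 sites 2.03 times and TEAD sites 1.51 times. Shuffles of these sites were 5.50 times as dense for CTCF, 1.5 times for NFI, 1.49 times for ETS, 1.17 times for the glucocorticoid receptor, 0.910 times for AP-1 and 0.855 times for TEAD, while REST shuffles had no match and RFX shuffles 1 in the regions and 1 in the flanks, too few for a comparison. MEF2 and GATA sites had 0.697 and 0.865 times the density of the flanks, whose GC content was 45.2% against 53.0% in the regions. Their shuffles had 0.252 and 0.639 times, so that relative to shuffles MEF2 sites were 2.76 times and GATA sites 1.36 times as dense in the regions as in the flanks. NKX2-5, TBX5 and ERR sites had 0.875, 0.662 and 0.686 times the density of the flanks, or 1.19, 0.789 and 0.850 times relative to shuffles. Of the CTCF sites in these regions 94.8% lay under footprints in replicate 1 and 92.3% in replicate 2, but so did 57.7% and 57.4% of their shuffles. Of the CREB sites 63.7% and 64.4% did, against 15.5% and 15.9% of shuffles. The share was lower than that of shuffles for the glucocorticoid receptor, with 5.46% in both replicates against 17.7% and 16.2%, and for GATA, with 8.21% and 8.24% against 11.2% and 10.4%. MEF2 had 10.1% and 11.1% against 13.2% and 12.2%, and FOX had 5.64% and 4.78% against 9.59% and 8.77%. In replicates 1 and 2 the share relative to shuffles was 0.781 and 0.937 times for ERR, 0.884 and 0.853 for MEIS, 0.97 in both for NKX2-5 and 1.01 and 1.05 for TBX5. It was 1.11 and 1.04 for TEAD, 1.48 and 1.51 for the HAND/TAL E-box and 1.59 and 1.70 for SRF.

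Footprint calls repeated less well than peaks and followed their strength. Of the footprints of replicate 1, 49.6% were at least 50% covered by footprints of replicate 2, and 54.0% the other way. Shifts along the chromosome gave a mean of 0.184%. In shared peaks the shares were 55.3% and 57.9%, against a mean of 23.2% after shifts inside those peaks. Over the 2 directions of 1 comparison they average 51.8% (SD 3.12) and 56.6% (SD 1.85), SDs that are not a spread between replicates. Footprints lay fully inside a peak of the same replicate in 83.8% ± 0.74 (SD, n = 2) of cases, and 82.0% ± 1.16 of peaks held a footprint. Promoter peaks held 2.84 ± 0.22 footprints and other peaks 2.01 ± 0.08, a difference larger than the spread between replicates. Promoter peaks were also the stronger ones, and no comparison at equal signal was made. In the weakest 25% of peaks 54.5% ± 3.55 held a footprint, and in the strongest 25% it was 98.9% ± 0.09.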

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

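Chosen after the data were seen were the tests with the smaller peak set, the stronger peaks against all peaks of the other replicate, footprints in the stronger shared peaks, peaks at the promoter of 1 gene only, CpG-matched and start-matched lists, GC-weighted windows and footprints at promoters. For the main results, 44 alternative values stayed within an SD, a sampling interval or 1.5 times the count, and 35 moved. The SD was over the 2 replicates, or for overlaps over the 2 directions of 1 comparison. The sampling intervals, for low-FDR bases and the signal correlation, treated bases or regions as independent and so were very narrow. These counts are therefore no measure of robustness. The cause was not tested except where the alternative's construction gives it.

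Stricter or looser overlap moved the shares by construction. Peak overlap was 51.0% with 80% reciprocal overlap, 87.4% among the stronger 50% of peaks and 94.9% for those against all peaks of the other replicate. Footprint overlap was 58.0% with any shared base and 23.2% with 80% reciprocal overlap, 56.6% in shared peaks and 66.7% in the stronger shared peaks. Footprints in peaks were 87.9% with any shared base and 67% with the smaller peak set. Overlap of low-FDR bases was 73.9% for the 50% with the lowest FDR and 63.1% as a share of regions. The signal correlation was 0.958 as Spearman's rho, 0.984 on untransformed values and 0.966 in the stronger shared peaks. Peaks at promoters were 20.4% with 500 bp, 30.2% with 2 kb, 29.1% with starts of all gene types, 35.9% among stronger peaks and 31.4% in the smaller set, and leaving out each replicate gave 24.0% to 26.2%.

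The 8 lists above the high percentile at promoters became 6 to 9 under the alternatives. The 2 lists below the low percentile became 4 with 5' ends alone, 5 with 500 bp, 5 with stronger peaks, 7 with the smaller set and 1 with peaks at the promoter of 1 gene. For regions around genes, 5 lists above became 3 without flanks (0 kb), and 0 below became 2 without flanks, 1 with stronger peaks, and 0 to 1 without each replicate.

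The 14 motifs above 1.5 became 7 against windows in peaks, 9 in footprints at promoters and 12 without flanks, but 20 against shuffles. They became 15 with GC-weighted windows, with footprints away from promoters and with replicate 1 alone. Ratios were missing for 6 motifs with windows in peaks, 4 at promoters, 5 without flanks and 3 with shuffles. The 7 motifs below 1, not counting ratios of 0 (HNF1 and SOX-OCT), became 13 at promoters, 12 without flanks, 4 with shuffles, 2 with windows in peaks and 4 with GC-weighted windows. Motifs that changed sides were MEF2 (shuffles 1.45, windows in peaks 1.29, GC-weighted 2.05), NKX2-5 (shuffles 1.49, windows in peaks 1.09), TBX5 (windows in peaks 1.13), FOX (shuffles 1.24), ERR (shuffles 2.39), TEAD (0 bp flank 0.737, promoters 0.862), SRF (0 bp flank 0.802, shuffles 0.798), MEIS (0 bp flank 0.889, promoters 0.824), HAND/TAL E-box (promoters 0.811), CACGTG E-box (shuffles 0.765), POU octamer (shuffles 2.96, GC-weighted 1.48), HNF4 (0 bp flank 0.860, promoters 0.570) and the glucocorticoid receptor (0 bp flank 0.193, windows in peaks 0.696, promoters 0.331). The values of the glucocorticoid receptor rest on 2 and 1 footprints without flanks and on 4 in each replicate at promoters. Its consensus is longer than the median footprint, 11 and 10 bp, so most footprints cannot hold it without flanks. For single lists and motifs, 326 values stayed, 218 moved and 23 changed sides, and for promoter values of named genes 421 stayed within the replicates' SD and 19 moved. Of named genes, 8 were no longer open at 5' ends alone, 9 with 500 bp, 4 with the smaller peak set and 1 with peaks at the promoter of 1 gene, and 4 became open with 2 kb. Read depth is not given in the sources used here, so its effect was not tested. No paired analysis was possible because there is a single group.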

Other observations

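The tests of base composition for TBX5 and ERR alone, and of a single scaling factor over GC content, were chosen after their results were seen. The bounds of the other tests were written beforehand, although the motifs tested had been picked for their ratios and 2 backgrounds had already changed their direction. The only biological explanation tested was a difference in cardiomyocyte nuclei between the replicates, since the design holds a single group.

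Of the 16 lists with at least 5 open genes, which leaves out hepatocytes and lung epithelium, cell division genes stood farthest from random lists in how the replicates differed, a comparison looked at after the values were seen. At promoters their median log2 ratio of replicate 1 to replicate 2 was 0.44. On the authors' scale 17 of 18 genes were higher in replicate 1. Of random lists matched on promoter signal and CpG content, 99.8% lay below that median. Housekeeping genes had 0.41, above 95.6%, and leukocyte genes 0.45, above 92.2%. Genes of fatty acid oxidation and respiration lay at the other end, with 0.24, above 7.19% of random lists.

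MEF2, GATA, NKX2-5, TBX5 and ERR sites, 5 kinds bound by heart factors, were less frequent in footprints than in windows 200 bp away, with a median log2 ratio of -0.61, while TEAD, MEIS, SRF and HAND/TAL E-box sites were not (1.05 to 1.24 times). The depletion was not limited to these 5. FOX sites had ratios of 0.577 in replicate 1 and 0.576 in replicate 2, and POU octamer sites had 0.726 and 0.665. With windows weighted to the GC content of footprints the median of the 5 was -0.056. That was just short of the 0 or above that base composition as the cause would give, so the test did not decide. GATA came to 1.00 ± 0.02 and NKX2-5 to 0.962 ± 0.05, so GC content may account for most of their depletion. MEF2 turned to 2.05 ± 0.04, an excess rather than a return to 1. TBX5 and ERR argued against base composition as their cause, since their ratios stayed at 0.804 or below in each replicate. Calls that miss bound sites stayed open, since sites of the 5 factors in accessible regions lay under footprints 0.859 times as often as their shuffles (median), and the part of the test that required 3 times for CTCF could decide nothing, because 57.7% and 57.4% of CTCF shuffles lay under footprints. Whether these factors leave footprints in this tissue cannot be told apart from calls that miss them.

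On the authors' scale replicate 1 had the higher signal in most shared regions, with a median log2 ratio of 0.31. The step of its signal was also the larger, 0.00709 against 0.00597 in replicate 2. The same number of steps thus gives a higher signal in replicate 1, so part of the ratio of 0.31 follows from the step alone. Over all peaks the median stood at 110 steps in replicate 1 and 122 in replicate 2. Shared regions were not compared in steps, so which replicate was higher in them is known on the authors' scale only. The ratio fell from 0.45 in the 20% of regions with the lowest GC content to 0.12 in the 20% with the highest. A GC effect that differed between libraries would give such a difference, 0.33, which does not depend on the step. On the authors' scale, though not necessarily in steps, replicate 1 stayed higher in each 20% of regions by GC content. Among promoters alone the 20% with the highest GC content were the other way (-0.042). For a single scaling factor, the difference by signal, 0.11, lay under the 0.15 set beforehand. Promoters against other regions gave 0.152, just over it, so that test did not settle the question. The difference of 0.33 over GC content argued against a single scaling factor as the whole cause. More cardiomyocyte nuclei in replicate 1 stayed open, since the ratio of the cardiomyocyte list, 0.39, lay above 94.7% of random lists, while those of cardiac transcription factors, 0.22, and of fatty acid oxidation and respiration lay above 35.1% and 7.19%. The bound set beforehand counted any position inside the central 95% of random lists against it, which was too wide, because a position inside that range (0.18 to 0.41) excludes no small difference.

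The 10 strongest regions away from promoters, led by those near Esp38 and in Lars2, may owe part of their signal to sequence present in several copies in the genome. Of the 10, 8 had another copy for over 50% of their 36-base words, against 0 of 100 random regions and 4 of the next 90. The region in Lars2 passed that limit narrowly, with 50.3%. In the 8 the median word occurred only 2 to 4 times in the reference, and whether so few copies could give signals this high was not tested. The regions near Gm42791 and Cox14, at 27.2 and 26.8, had no such copies, and nor had the region near Nacc2, at 25.9. Only exact words of the C57BL/6J reference were searched, so diverged copies and copies absent from it were not excluded.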
